A study of Homo sapiens with 12 samples.

How the data were processed

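Gene expression was measured in T98G, an established human glioblastoma cell line, on 12 one-colour oligonucleotide arrays of 54675 probe sets, a probe set being a small group of probes that reads one transcript. Per the labels, the arrays came from 4 groups of 3: Monolayer (adherent cells at 60% confluence), Spheroid (cells grown 4 days in suspension over agarose), Spheroid Recovery (spheroids given fresh medium after 2 weeks of storage) and Monolayer Recovery (cells that had grown out as an adherent layer for 7 days). Total RNA was the material on every array. The group and the replicate number of each array were taken from its title. The labels say that samples were in triplicate but do not say that the 3 came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

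The values used were the intensities that the authors deposited, one linear intensity per probe set and array, rounded to whole numbers. The background correction, normalization and summary steps behind the deposited intensities are not given in the sources used here. The median intensity was 12 or 13 on every array, and no pair of arrays held identical values. Between 62.0% and 77.1% of probe sets on an array lay above the brightest of 27 control probe sets for bacterial transcripts that were not spiked in, which read 4 to 9. Arrays carry no read depth, and the number of arrays limits the precision.

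Probe sets were named from the platform annotation, which gave 41091 of them a single gene symbol and 1801 several. A further 11721 were not named here, and 62 were controls. Of the singly named probe sets, 41037 matched a current gene table by Entrez identifier and 54 did not, and 0 symbols changed. Only singly named probe sets were used for genes. Each of the 19775 genes was represented by the probe set with the highest mean over all 12 arrays, and the 25% of genes with the lowest mean were left out, which left 14832. Genome positions were not used here.

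Intensities were analysed as log2(value + 16), so that fold changes are on that scale and understate the change of dim genes. Each of the 6 comparisons was tested with limma 3.58.1 in R 4.3.3, using 1 linear model over all 12 arrays, empirical Bayes variances with an intensity trend and robust estimation, a two-sided test, Benjamini-Hochberg adjustment over the 14832 genes and a threshold of 0.05. A moderated F test over the 3 contrasts with Monolayer asked whether a gene differed anywhere. Arrays of all groups shared 1 estimate of the spread. Errors of log2 changes are standard errors from this model, and errors of intensities are SD over 3 arrays.

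A total of 39 gene lists of 1056 members, 879 of them tested, were written from textbook knowledge. They covered the cell cycle, metabolism, stress responses, protein synthesis and breakdown, signalling targets, matrix and adhesion, and markers of neurons, astrocytes, oligodendrocytes, endothelium and pericytes, epithelium, leukocytes and stem cells. Each list was tested with camera, which sets a list against all other genes, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 39 lists of a comparison. Counts of members called are given with adjustment over all genes and adjusted over the list alone. Camera with the correlation estimated for each list (statmod 1.5.0) and fry, which asks whether a list's genes move one way on balance, were run as alternatives.

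Genes are named by a fixed rule. For each comparison these were the 5 genes with the largest rise and the 5 with the largest fall among those that passed the test with no overlap between the groups' arrays. For each list passing camera they were up to 3 members called in the list's direction and 1 called the other way, of which the text gives the largest changes first. A panel of genes fixed with the rule could be named anywhere, and a gene whose other probe sets had the opposite sign is named with that fact. Of the panel, CA9 and HSPA1A had no singly named probe set, FOS and GFAP were too dim to be tested, and panel genes that were not tested are not reported. The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, with exceptions. These were 2 alternatives, a fit without the Spheroid Recovery arrays and a choice among probe sets designed on NM_ reference transcripts only. Further exceptions were the tests that the closing section names as chosen after the results were seen. The closing tests of EST probe sets, long non-coding genes and ARRDC4 were also added later, for patterns seen in the results. Their predictions were written before those tests were run.

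The pipeline was tested on simulated data for Spheroid against Monolayer with 200 of 14832 genes changed. It recovered 64 of 67 genes changed by 1.5-fold, 67 of 67 changed by 2-fold and 66 of 66 changed by 4-fold, with 7 false calls among 204. A simulated list shifted by 0.3 on the log2 scale passed, and 0 of 38 unshifted lists did. Genes were simulated independently of each other, and the 200 changed ones were drawn from genes above the median intensity. The simulation therefore tests neither lists of correlated genes nor the recovery of dim genes. For comparisons that share arrays, 20 simulations of unchanged groups gave the overlap that sharing alone produces.

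Other settings tried were offsets of 1 and 64, quantile normalization, median centring, no filter on dim genes, the dimmest 50% left out, the mean of all probe sets of a gene, probe sets with names ending in _x_at left out, a fit without trend and robust estimation, array weights, a fit on only the arrays of the groups compared, the replicate number as a block, a threshold of 0.01, a minimum of 2-fold, a limma treat test against 1.5-fold, and each array left out in turn. RNA integrity was read from control probe sets at the 3' and 5' ends of ACTB, GAPDH and the control transcript HUMISGF3A, as the log2 ratio of 3' over 5' intensity. Those ratios were compared by exact two-sided permutation tests, for which 3 against 3 arrays cannot give a p below 0.1. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.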

Results

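The arrays followed T98G glioblastoma cells through a cycle of spheroid growth, storage at ambient temperature and regrowth. Monolayer cells were attached and at 60% confluence in medium with 10% serum, Spheroid cells had grown for 4 days in suspension over agarose, and the spheroids were then kept 2 weeks at room temperature in the dark, without medium and under vacuum. Spheroid Recovery cells had been given medium with 15% serum after storage, and Monolayer Recovery cells had grown out as an attached layer for 7 days. The labels do not say whether the Spheroid arrays were taken before or after storage, nor how long after feeding the Spheroid Recovery RNA was taken. Each group had 3 arrays, with a median intensity of 12 or 13 on each array.

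Of 14832 genes tested, 10385 (70.0%) differed among the groups by limma's F test. Arrays of one group correlated at 0.993 to 0.997, and between groups the mean correlation fell from 0.976 for Monolayer with Monolayer Recovery to 0.903 for Monolayer with Spheroid Recovery. The first principal component, with 61.0% of the variance, set Spheroid Recovery apart from the other groups, and the next, with 25.6%, set Spheroid apart from Monolayer. Control probe sets at the 3' and 5' ends of ACTB, the beta-actin transcript, differed by 2.73 ± 0.08 on the log2 scale in Monolayer, 4.62 ± 0.21 in Spheroid, 4.97 ± 0.27 in Spheroid Recovery and 3.85 ± 0.08 in Monolayer Recovery (SD, n = 3). For GAPDH the same difference lay between 0.27 and 0.36 in every group. Each ACTB difference from Monolayer had an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give.

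**Figure D1:**
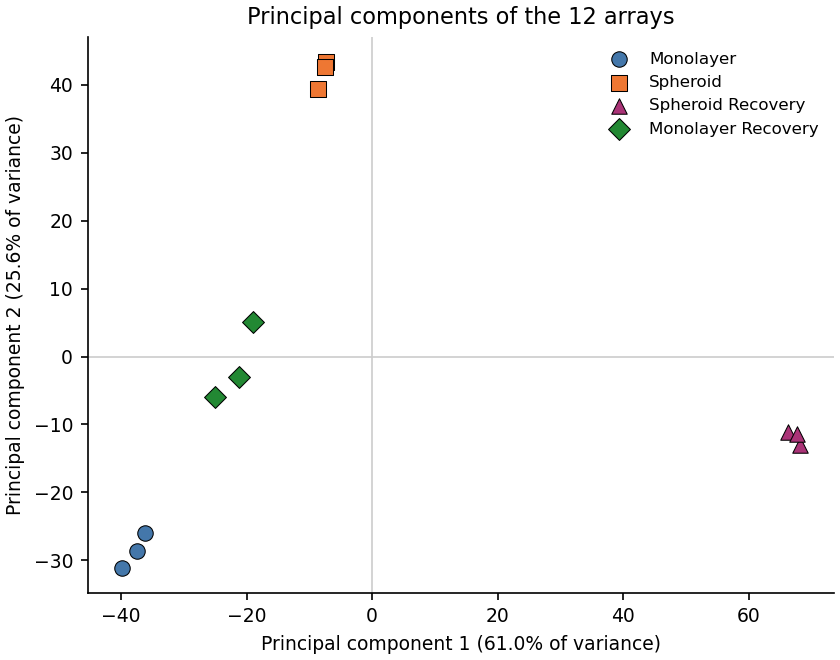
Principal component 1 (horizontal, 61.0% of variance) and principal component 2 (vertical, 25.6% of variance) of the log2 intensities, with 1 point per array coloured by group. The 3 Spheroid Recovery arrays lie alone at the right, and the Monolayer Recovery arrays lie between Monolayer and Spheroid.

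**Figure D2:**
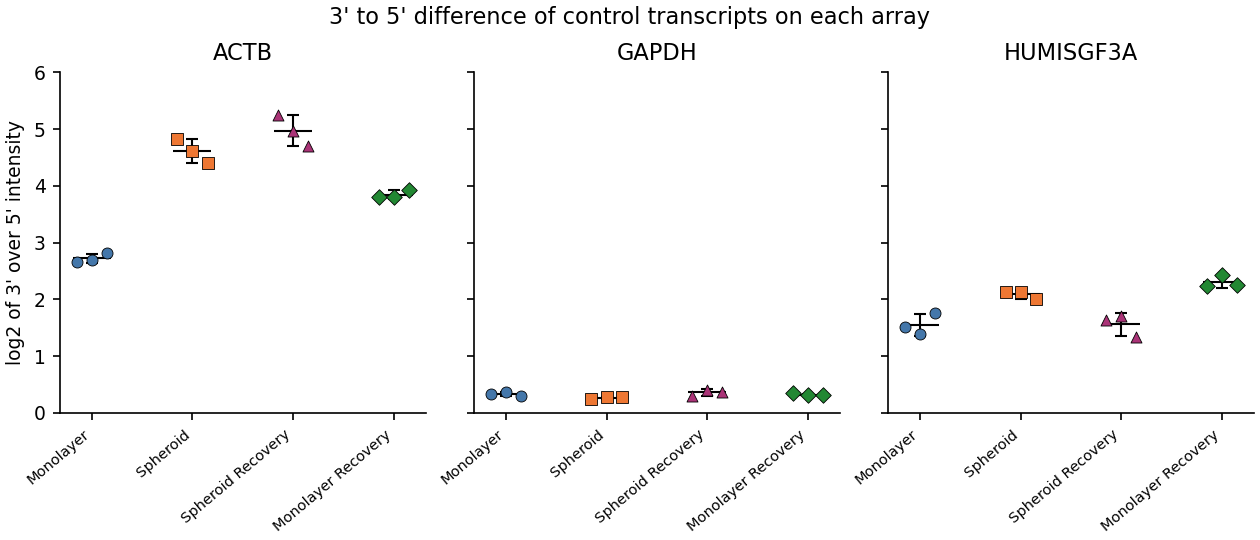
Log2 ratio of 3' over 5' control intensity (vertical) for ACTB, GAPDH and HUMISGF3A in each group (horizontal), with points for arrays, and a bar and whiskers for the mean and SD of 3 arrays. The ACTB ratio has means of 2.73 in Monolayer and 4.97 in Spheroid Recovery, the GAPDH ratio stays between 0.27 and 0.36, and the HUMISGF3A ratio has means of 1.55 and 1.56 in those groups.

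Spheroid was compared with Monolayer to ask how cells grown in suspension differed from the starting culture. Growth time, cell density and storage, if it came before these arrays, cannot be told apart here from suspension. Genes of cell division were lower and genes of oxidative stress defence, oxygen response and growth arrest were higher in Spheroid. With an estimated correlation mitosis held (0.022), while adjusted p = 0.103 for NRF2, 0.168 for hypoxia and 0.114 for quiescence with an estimated correlation. The largest rise was in PI15, a secreted peptidase inhibitor, at an intensity of 2340.0 ± 245 against 39 ± 7.55 (log2 change 5.43 ± 0.14, SE). TNFRSF11B, the decoy receptor osteoprotegerin, rose by 4.17 ± 0.13, GLDN, which encodes gliomedin, by 4.16 ± 0.09, the chemokine gene CCL8 by 3.97 ± 0.09 and SPTSSA, a subunit of serine palmitoyltransferase, by 3.92 ± 0.14. The largest falls were in CCN1, a matricellular protein and YAP target (-4.61 ± 0.10), DKK1, a secreted Wnt antagonist (-4.26 ± 0.13), the interleukin 7 receptor gene IL7R (-4.04 ± 0.12), the adhesive glycoprotein gene THBS1 (-3.71 ± 0.17) and STC2, a secreted stanniocalcin (-3.70 ± 0.10).

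Of the mitosis list, 41 of 42 tested genes fell and 0 rose (41 and 0 adjusted over the list alone). The largest falls were in CDC20, an activator of the anaphase-promoting complex (-2.79 ± 0.11), FOXM1, a transcription factor of G2 and M phase genes (-2.59 ± 0.14), and the proliferation marker MKI67 (-2.43 ± 0.12). Of the DNA replication list, 31 of 38 tested genes fell and 2 rose (31 and 2 adjusted over the list alone), led by GINS2, part of the replicative helicase (-2.41 ± 0.15), and the transcription factor E2F1 (-1.85 ± 0.11). CCND1, the gene of cyclin D1, stood at -2.22 ± 0.08. Among quiescence genes and CDK inhibitors 14 of 19 tested genes rose and 2 fell (14 and 2 adjusted over the list alone). PDGFRA, a growth factor receptor, read 137 ± 19.1 against 8.33 ± 0.577, and its Monolayer level was within the range of the unspiked controls, so that the change is a lower bound (2.64 ± 0.08, the sign was the opposite at 1 of 1 other probe sets). TXNIP, an inhibitor of thioredoxin, rose by 2.38 ± 0.09, and the antiproliferative gene BTG1 by 2.01 ± 0.07. By camera the adjusted p was 1.57e-21 for mitosis, 1.29e-08 for replication and 4.04e-06 for quiescence. For replication adjusted p = 0.103 with an estimated correlation, and for quiescence adjusted p = 0.114 with an estimated correlation, while mitosis held at 0.022.

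In the NRF2 list, 19 of 28 tested genes rose and 3 fell (19 and 3 adjusted over the list alone). Among them were GCLC, the catalytic subunit of glutathione synthesis, at 2.997 ± 0.08 and mitochondrial superoxide dismutase SOD2 at 2.52 ± 0.06, against the glutathione peroxidase GPX1 at -1.09 ± 0.11. Of hypoxia genes, 21 of 33 tested genes rose and 7 fell (21 and 8 adjusted over the list alone). Examples were the glucose transporter SLC2A3 at 2.88 ± 0.09, the angiogenic factor VEGFA at 2.68 ± 0.13 and the MYC antagonist MXI1 at 2.59 ± 0.11. STC2, of the same list, had the opposite direction. Of autophagy and lysosome genes, 21 of 35 tested genes rose and 5 fell (21 and 6 adjusted over the list alone), among them the autophagosome gene MAP1LC3B (1.41 ± 0.09, the sign was the opposite at 1 of 1 other probe sets). Of interferon-stimulated genes, 18 of 33 tested genes rose and 5 fell (21 and 5 adjusted over the list alone). Within this list were the membrane protein gene IFITM1 at 2.11 ± 0.07 and IFIT2, which restricts viral translation, at 1.27 ± 0.12, against the GTPase gene GBP1 at -1.43 ± 0.12. The adjusted p from camera was 1.37e-08, 0.000342, 0.000269 and 0.000883 for these lists in that order. In that order, adjusted p = 0.103, 0.168, 0.14 and 0.28 with an estimated correlation.

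Of cholesterol synthesis genes, 15 of 18 tested genes fell and 0 rose (15 and 0 adjusted over the list alone), led by ACAT2, a thiolase (-2.23 ± 0.11), and the isomerase EBP (-1.63 ± 0.07, the sign was the opposite at 1 of 3 other probe sets), with a camera adjusted p of 3.28e-06 that held with an estimated correlation (0.022). Of proteasome genes, 21 of 26 tested genes fell and 0 rose (21 and 0 adjusted over the list alone), with PSMD2 at -1.52 ± 0.09. Of ribosome biogenesis genes, 21 of 27 tested genes fell and 0 rose (21 and 0 adjusted over the list alone), with the nucleolar protein gene NOP58 at -1.24 ± 0.12. Of heat shock proteins, 15 of 19 tested genes fell and 1 rose (17 and 1 adjusted over the list alone), with HSPA4 at -1.45 ± 0.07. Of aminoacyl-tRNA synthetases, 14 of 17 tested genes fell and 2 rose (14 and 2 adjusted over the list alone), with the glycyl enzyme GARS1 at -1.27 ± 0.08. Of actin and SRF/YAP targets, 19 of 27 tested genes fell and 2 rose (20 and 2 adjusted over the list alone). The list included AMOTL2, a YAP target, at -1.58 ± 0.11 after CCN1, against MYLK, the myosin light chain kinase (0.95 ± 0.07, the sign was the opposite at 1 of 1 other probe sets). Of the metal-binding metallothioneins, 7 of 7 tested genes fell and 0 rose (7 and 0 adjusted over the list alone), led by MT1E (-1.18 ± 0.10). Of glycolysis genes, 12 of 18 tested genes fell and 2 rose (13 and 2 adjusted over the list alone). Its members included phosphofructokinase PFKP (-1.57 ± 0.12, the sign was the opposite at 1 of 1 other probe sets) and enolase ENO1 (-1.12 ± 0.07). Of oxidative phosphorylation genes, 22 of 36 tested genes fell and 4 rose (22 and 4 adjusted over the list alone), led by the ATP synthase subunit ATP5F1B (-1.01 ± 0.08). Camera gave an adjusted p of 6.37e-07 for proteasome, 1.45e-06 for ribosome biogenesis, 2.39e-05 for heat shock proteins, 0.000342 for synthetases, 3.25e-05 for actin, 0.00108 for metallothioneins, 0.00649 for glycolysis and 0.0176 for oxidative phosphorylation. In the same order, adjusted p = 0.103, 0.114, 0.114, 0.28, 0.103, 0.115, 0.307 and 0.608 with an estimated correlation.

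Of single genes fixed in the panel, the immediate early transcription factor EGR1 rose from 548 to 2985 (2.41 ± 0.08), the matrix gene FN1 (fibronectin) by 2.06 ± 0.08 and the collagenase MMP1 by 2.18 ± 0.11, and the intermediate filament gene VIM (vimentin) changed by -1.23 ± 0.06. The cold-inducible RNA-binding protein gene CIRBP changed by 0.24 ± 0.05 (the sign was the opposite at 1 of 4 other probe sets). For RBM3, of the same family, the change was 0.10 ± 0.06 and did not pass the test (adjusted p = 0.126, the sign was the opposite at 1 of 1 other probe sets), and with the mean of all its probe sets it was -0.00061. The largest adjusted p of a gene named here as changed was 0.000159. In all, 7742 genes passed, 3566 higher and 4176 lower. Of these 1033 and 541 changed by at least 2-fold. The groups' arrays did not overlap for 59.3% of genes, where chance gives 10%. The ACTB control ratio was wider in Spheroid by 1.89 ± 0.13 (SE) and the HUMISGF3A ratio by 0.54 ± 0.12, beside all of these lists. With only NM_ probe sets, an alternative chosen after the data were seen, oxidative phosphorylation no longer passed (adjusted p = 0.481).

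Spheroid Recovery was compared with Monolayer to ask how stored and refed spheroids differed from the starting culture. Genes of cell division, glycolysis and matrix were lower, and lysosomal genes were higher. Mitosis held with an estimated correlation (0.0429), while adjusted p = 0.133 for glycolysis, 0.106 for matrix and 0.133 for lysosome with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell from 2536 to 29.7 (-5.80 ± 0.08), and large falls were also seen in HMMR, a hyaluronan receptor of the mitotic spindle (-4.99 ± 0.09), DIAPH3, a formin (-4.97 ± 0.11), the cyclin gene CCNB1 (-4.88 ± 0.09) and EHD2, a protein of caveolae (-4.69 ± 0.08). The largest rises were in the long non-coding RNA LINC-PINT (4.30 ± 0.09), SLF2, a factor for SMC5/6 complex loading (4.23 ± 0.12, the sign was the opposite at 2 of 3 other probe sets), the sorting nexin SNX30 (3.98 ± 0.13), MATR3, a nuclear matrix protein that binds RNA (3.82 ± 0.09), and LOC100289230 (3.68 ± 0.09).

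Every tested mitosis gene was lower, since 42 of 42 tested genes fell and 0 rose (42 and 0 adjusted over the list alone), with the DNA topoisomerase TOP2A at -4.49 ± 0.14 after HMMR and CCNB1. Of replication genes, 36 of 38 tested genes fell and 1 rose (36 and 1 adjusted over the list alone), with thymidylate synthase TYMS at -4.37 ± 0.10 (the sign was the opposite at 1 of 2 other probe sets) after RRM2. Camera's adjusted p was 1e-21 for mitosis, which held with an estimated correlation (0.0429), and 1.53e-10 for replication, for which adjusted p = 0.106 with an estimated correlation. CCND1 stood at -1.98 ± 0.08.

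Of glycolysis genes, 16 of 18 tested genes fell and 1 rose (16 and 1 adjusted over the list alone). In this list were glucose-6-phosphate isomerase GPI at -2.11 ± 0.12 and triosephosphate isomerase TPI1 at -1.99 ± 0.08, while GAPDH fell from 3724 to 1578 (-1.23 ± 0.05). Of oxidative phosphorylation genes, 28 of 36 tested genes fell and 1 rose (28 and 1 adjusted over the list alone), led by the complex I subunit NDUFB8 (-3.18 ± 0.11). Of the citric acid cycle, 12 of 18 tested genes fell and 2 rose (12 and 2 adjusted over the list alone), led by the succinate-CoA ligase subunit SUCLG1 (-2.43 ± 0.09). Of cholesterol synthesis genes, 13 of 18 tested genes fell and 2 rose (13 and 2 adjusted over the list alone), led by ACAT2 (-2.51 ± 0.11). Of fatty acid synthesis, 7 of 12 tested genes fell and 1 rose (7 and 1 adjusted over the list alone), led by the elongase ELOVL6 (-3.20 ± 0.11, the sign was the opposite at 1 of 2 other probe sets). By camera the adjusted p was 8.62e-06, 1.88e-05, 0.0198, 0.00696 and 0.0198 for these lists in that order. In that order, adjusted p = 0.133, 0.364, 0.413, 0.106 and 0.177 with an estimated correlation.

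Of heat shock proteins, 16 of 19 tested genes fell and 1 rose (16 and 1 adjusted over the list alone). Members included the small chaperone HSPB1 at -3.33 ± 0.09 and the mitochondrial chaperonin HSPD1 at -2.86 ± 0.07. Of aminoacyl-tRNA synthetases, 16 of 17 tested genes fell and 1 rose (16 and 1 adjusted over the list alone), led by FARSB (-1.84 ± 0.10, the sign was the opposite at 1 of 1 other probe sets). Of proteasome genes, 20 of 26 tested genes fell and 4 rose (20 and 4 adjusted over the list alone), led by PSMB2 (-2.18 ± 0.10, the sign was the opposite at 2 of 2 other probe sets), while PSMD11 stood at 2.69 ± 0.08 (the sign was the opposite at 1 of 1 other probe sets). Of ribosome biogenesis genes, 21 of 27 tested genes fell and 2 rose (21 and 2 adjusted over the list alone), led by nucleolin NCL (-1.96 ± 0.08, the sign was the opposite at 1 of 1 other probe sets). Of metallothioneins, 6 of 7 tested genes fell and 0 rose (6 and 0 adjusted over the list alone), led by MT1E (-2.14 ± 0.10). Of endoplasmic reticulum chaperones, 14 of 24 tested genes rose and 6 fell (14 and 7 adjusted over the list alone). Among them were EDEM1, of the degradation pathway for misfolded proteins, at 2.81 ± 0.14 and DNAJB9 at 2.28 ± 0.10, against the disulfide isomerase PDIA4 at -2.18 ± 0.07. The adjusted p from camera was 1.88e-05 for heat shock proteins, 8.8e-05 for synthetases, 0.000374 for proteasome, 0.000811 for ribosome biogenesis, 0.000305 for metallothioneins and 0.0263 for endoplasmic reticulum chaperones. In that order, adjusted p = 0.106, 0.221, 0.177, 0.221, 0.106 and 0.155 with an estimated correlation.

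Of collagens and matrix proteins, 22 of 35 tested genes fell and 3 rose (22 and 3 adjusted over the list alone). Examples were the collagen genes COL4A2 at -3.51 ± 0.15 and COL5A2 at -3.13 ± 0.10. Of actin and SRF/YAP targets, 20 of 27 tested genes fell and 2 rose (20 and 2 adjusted over the list alone). Within this list were the non-muscle myosin MYH10 at -3.57 ± 0.10 and the tropomyosin TPM2 at -2.89 ± 0.07. Of integrins and focal adhesion genes, 17 of 28 tested genes fell and 5 rose (17 and 5 adjusted over the list alone), led by the tensin TNS3 (-2.55 ± 0.11). VIM fell from 2209 to 397 (-2.43 ± 0.06). Camera gave an adjusted p of 0.000305, 4.15e-05 and 0.027 for these lists in that order. In that order, adjusted p = 0.106, 0.106 and 0.177 with an estimated correlation.

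Of autophagy and lysosome genes, 23 of 35 tested genes rose and 6 fell (23 and 6 adjusted over the list alone). The list included acid ceramidase ASAH1 at 2.66 ± 0.12 and the lysosomal membrane protein LAMP2 at 2.31 ± 0.09. Of p53 targets, 11 of 22 tested genes rose and 4 fell (11 and 4 adjusted over the list alone), led by TP53INP1, a stress-induced regulator of p53 (2.43 ± 0.10). Of the cold-inducible RNA-binding proteins, 5 of 6 tested genes rose and 1 fell (5 and 1 adjusted over the list alone). In that list the splicing factor SRSF5 stood at 1.94 ± 0.12, RBM3 at 0.82 ± 0.06 (the sign was the opposite at 1 of 1 other probe sets), CIRBP at 0.79 ± 0.05 (the sign was the opposite at 2 of 4 other probe sets) and HNRNPDL at -0.81 ± 0.07 (the sign was the opposite at 1 of 4 other probe sets). Camera's adjusted p was 8.8e-05 for lysosome, 0.027 for p53 and 0.0437 for cold-inducible genes. In that order, adjusted p = 0.133, 0.177 and 0.248 with an estimated correlation. The cold-inducible list did not pass after quantile normalization (adjusted p = 0.0585), median centring (0.139), without Monolayer replicate 1 (0.0509) or without Spheroid Recovery replicate 3 (0.0545). Endoplasmic reticulum chaperones did not pass after quantile normalization (adjusted p = 0.0532) or median centring (0.101), nor p53 targets after median centring (0.0988).

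In the panel, VEGFA stood at 1.83 ± 0.13, the stress transcription factor DDIT3 at 0.76 ± 0.11, the hyaluronan receptor CD44 at 0.67 ± 0.05 (the sign was the opposite at 2 of 10 other probe sets), asparagine synthetase ASNS at -1.97 ± 0.11 and EGR1 at -1.39 ± 0.08. Of the genes named as changed, the largest adjusted p was 2.9e-06. In all, 8401 genes passed, 3536 higher and 4865 lower. Of these 1274 and 1613 changed by at least 2-fold. The arrays did not overlap for 59.1% of genes, where chance gives 10%. Higher genes made up 42.1% of those called, but 67.9% after median centring, which moved the median change of all genes from -0.04 to 0.15. Camera sets a list against the other genes, so its result is relative to such a shift. The ACTB control ratio was wider in Spheroid Recovery by 2.25 ± 0.17 (SE), beside all of these lists. With only NM_ probe sets, chosen after the data were seen, the citric acid cycle (adjusted p = 0.405), fatty acid synthesis (0.413), endoplasmic reticulum chaperones (0.129) and p53 targets (0.211) no longer passed.

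Monolayer Recovery was compared with Monolayer to ask whether regrown cells differed from the starting culture. The labels give serum of 10% for growth and 15% for recovery, and 5% non-essential amino acids. Differences of medium or cell density cannot be told apart here from those of the storage cycle. Genes of endoplasmic reticulum protein folding and of amino acid supply were higher, and genes of cell division and heat shock proteins were lower. HERPUD1, a membrane protein of endoplasmic reticulum-associated degradation, read 1949 ± 73.1 against 101 ± 8.89 (4.07 ± 0.08). ASNS rose by 3.42 ± 0.11, the oxidoreductase ERO1B by 3.12 ± 0.13, the co-chaperone DNAJB9 by 3.05 ± 0.10 and SEL1L, part of a degradation ligase complex, by 3.02 ± 0.10. The largest falls were in TXNIP (-2.89 ± 0.09), the BMP antagonist NOG (-2.29 ± 0.10, a lower bound on the size of the fall since its Monolayer Recovery level of 8.67 was within the range of unspiked controls), GINS2 (-2.27 ± 0.15), PMEPA1, a TGF-beta target (-2.20 ± 0.09), and WWC1, a Hippo pathway regulator (-2.19 ± 0.11, the sign was the opposite at 1 of 3 other probe sets).

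Of endoplasmic reticulum chaperones, 22 of 24 tested genes rose and 0 fell (22 and 0 adjusted over the list alone), and HSPA5, the chaperone BiP, rose from 853 to 6010.0 (2.79 ± 0.06). Of ATF4 and amino acid response genes, 26 of 28 tested genes rose and 0 fell (26 and 0 adjusted over the list alone). Its members included the pseudokinase TRIB3 at 2.36 ± 0.09 and the cystathionine gamma-lyase CTH at 2.34 ± 0.10 after ASNS, and DDIT3 stood at 1.92 ± 0.11. Of mitosis genes, 40 of 42 tested genes fell and 0 rose (40 and 0 adjusted over the list alone), led by MKI67 (-1.97 ± 0.12) and FOXM1 (-1.58 ± 0.14). Of replication genes, 35 of 38 tested genes fell and 0 rose (36 and 0 adjusted over the list alone), with MCM3, a helicase subunit, at -1.49 ± 0.14 after GINS2. Of heat shock proteins, 17 of 19 tested genes fell and 0 rose (17 and 0 adjusted over the list alone), led by HSPH1 (-1.47 ± 0.10) and HSPB1 (-1.17 ± 0.09). By camera the adjusted p was 5.09e-23 for chaperones of the endoplasmic reticulum, 2.59e-21 for ATF4 genes, 2.59e-21 for mitosis, 1.38e-14 for replication and 3.96e-09 for heat shock proteins. These 5 calls held with an estimated correlation (adjusted p = 0.000364, 0.0163, 0.0163, 0.0261 and 0.0383).

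Of NRF2 genes, 17 of 28 tested genes rose and 4 fell (17 and 4 adjusted over the list alone). In this list were GCLC at 1.96 ± 0.08 and the cystine transporter SLC7A11 at 1.59 ± 0.07, against GPX1 at -1.37 ± 0.11. Of aminoacyl-tRNA synthetases, 10 of 17 tested genes rose and 6 fell (11 and 6 adjusted over the list alone). Members included SARS1 at 2.00 ± 0.10 and WARS1 at 1.41 ± 0.11 against HARS1 at -0.80 ± 0.09. Of quiescence genes, 8 of 19 tested genes rose and 3 fell (9 and 3 adjusted over the list alone), with DDIT4, an inhibitor of mTOR signalling, at 2.24 ± 0.08, while TXNIP went the other way. Of proteasome genes, 20 of 26 tested genes fell and 1 rose (22 and 1 adjusted over the list alone), with PSMD2 at -1.10 ± 0.09. Of ribosome biogenesis genes, 19 of 27 tested genes fell and 1 rose (21 and 2 adjusted over the list alone), with NOP58 at -1.24 ± 0.12. Of metallothioneins, 6 of 7 tested genes fell and 0 rose (6 and 0 adjusted over the list alone), led by MT2A (-0.96 ± 0.07). Of oxidative phosphorylation genes, 26 of 36 tested genes fell and 2 rose (26 and 2 adjusted over the list alone), led by NDUFV1 (-0.82 ± 0.11, the sign was the opposite at 1 of 1 other probe sets). Of glycolysis genes, 12 of 18 tested genes fell and 2 rose (14 and 2 adjusted over the list alone), led by PFKP (-0.99 ± 0.12, the sign was the opposite at 1 of 1 other probe sets). Of the citric acid cycle, 12 of 18 tested genes fell and 2 rose (12 and 2 adjusted over the list alone), led by DLST (-0.88 ± 0.12). Of ribosomal proteins, 21 of 37 tested genes fell and 1 rose (23 and 1 adjusted over the list alone), led by RPL35 (-0.78 ± 0.08). Of actin and SRF/YAP targets, 13 of 27 tested genes fell and 4 rose (13 and 4 adjusted over the list alone), led by the myosin MYH9 (-1.08 ± 0.09).

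For these lists camera's adjusted p was 7.75e-07 (NRF2), 0.0132 (synthetases), 0.00237 (quiescence), 2.26e-06 (proteasome), 4.74e-05 (ribosome biogenesis), 0.000203 (metallothioneins), 5.17e-05 (oxidative phosphorylation), 0.00237 (glycolysis), 0.0416 (citric acid cycle), 0.000863 (ribosomal proteins) and 0.0345 (actin). In the same order, adjusted p = 0.103, 0.462, 0.359, 0.103, 0.208, 0.103, 0.439, 0.359, 0.478, 0.51 and 0.36 with an estimated correlation. Synthetases did not pass after median centring (adjusted p = 0.0602), actin targets without Monolayer Recovery replicate 1 (0.0849) or Monolayer replicate 3 (0.0577), and the citric acid cycle without Monolayer Recovery replicate 2 (0.0564), without Monolayer replicate 2 (0.0524), without the Spheroid Recovery arrays (0.0509) or with only NM_ probe sets (0.187). Quiescence genes did not pass with only NM_ probe sets (0.257).

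In the panel, CCND1 stood at -1.88 ± 0.08, VEGFA at 2.17 ± 0.13 (the sign was the opposite at 1 of 3 other probe sets), the cytokine gene IL6 at 0.56 ± 0.08 and VIM at -0.77 ± 0.06. The chemokine gene CXCL8 stood at 0.66 ± 0.13, and without probe sets ending in _x_at at 0.13, which did not pass (adjusted p = 0.188). RBM3 stood at 0.28 ± 0.06, and CIRBP at 0.02 ± 0.05, which did not pass the test (adjusted p = 0.723, the sign was the opposite at 4 of 4 other probe sets). After median centring CIRBP stood at 0.12 and passed (adjusted p = 0.0467), and with the mean of all its probe sets it stood at -0.11. Adjusted p was at most 0.000484 for the genes named as changed. In all, 6073 genes passed, 2346 higher and 3727 lower. Of these 259 and 281 changed by at least 2-fold. The arrays did not overlap for 46.2% of genes, where chance gives 10%. Higher genes made up 38.6% of those called, and 59.0% after median centring. The ACTB control ratio was wider in Monolayer Recovery by 1.12 ± 0.06 (SE) and the HUMISGF3A ratio by 0.76 ± 0.12, beside all of these lists.

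**Figure D3:**
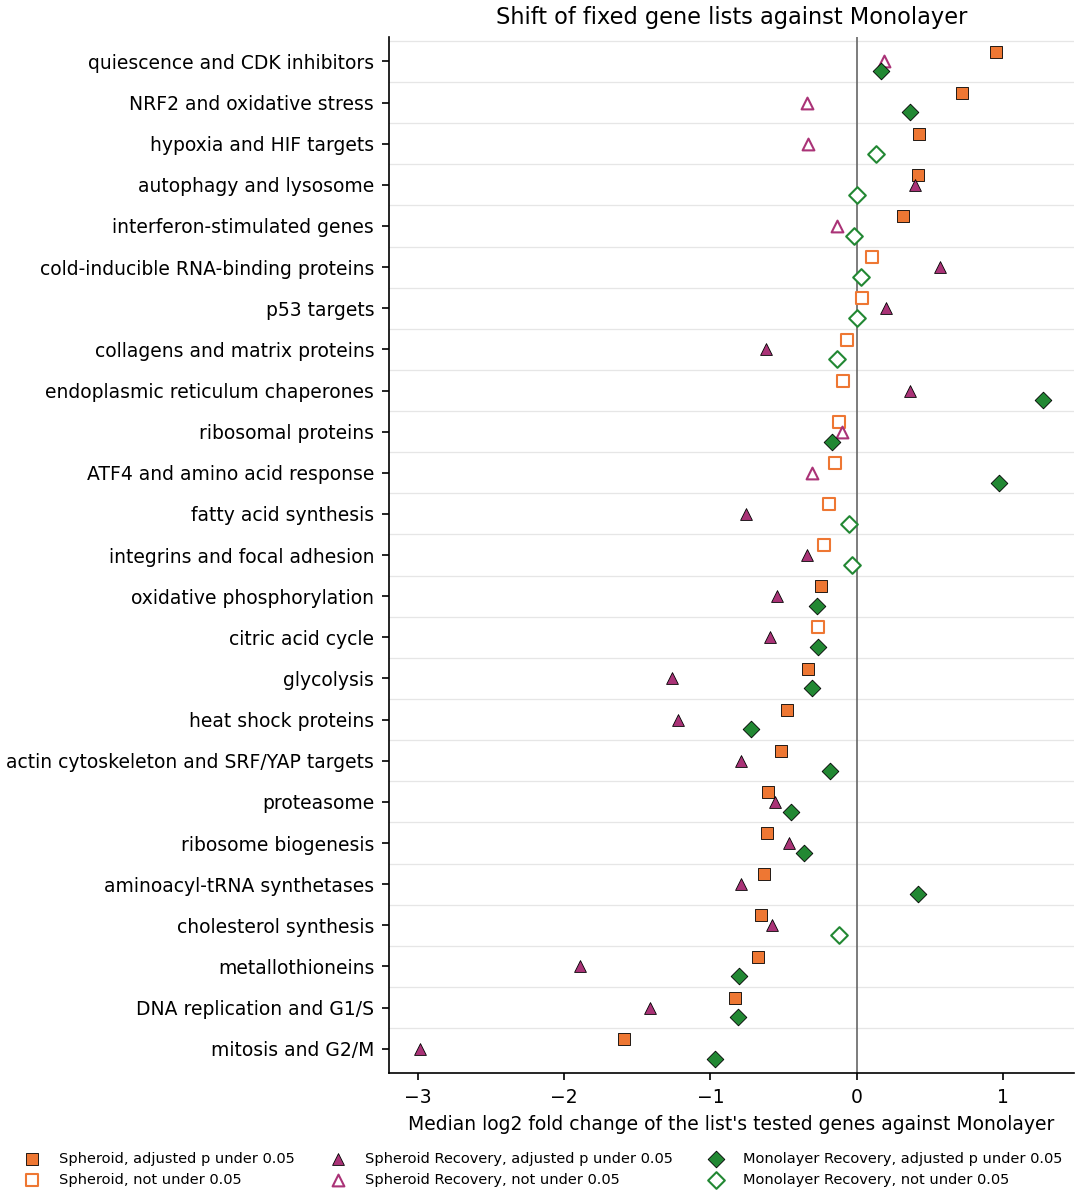
Median log2 fold change against Monolayer (horizontal) of the tested genes of each fixed list (vertical) that passed camera in at least 1 of the 3 comparisons, with a symbol per group, filled where camera's adjusted p was under 0.05. Mitosis genes have medians of -1.59 in Spheroid, -2.98 in Spheroid Recovery and -0.97 in Monolayer Recovery, and endoplasmic reticulum chaperones have a median of 1.27 in Monolayer Recovery.

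**Figure D4:**
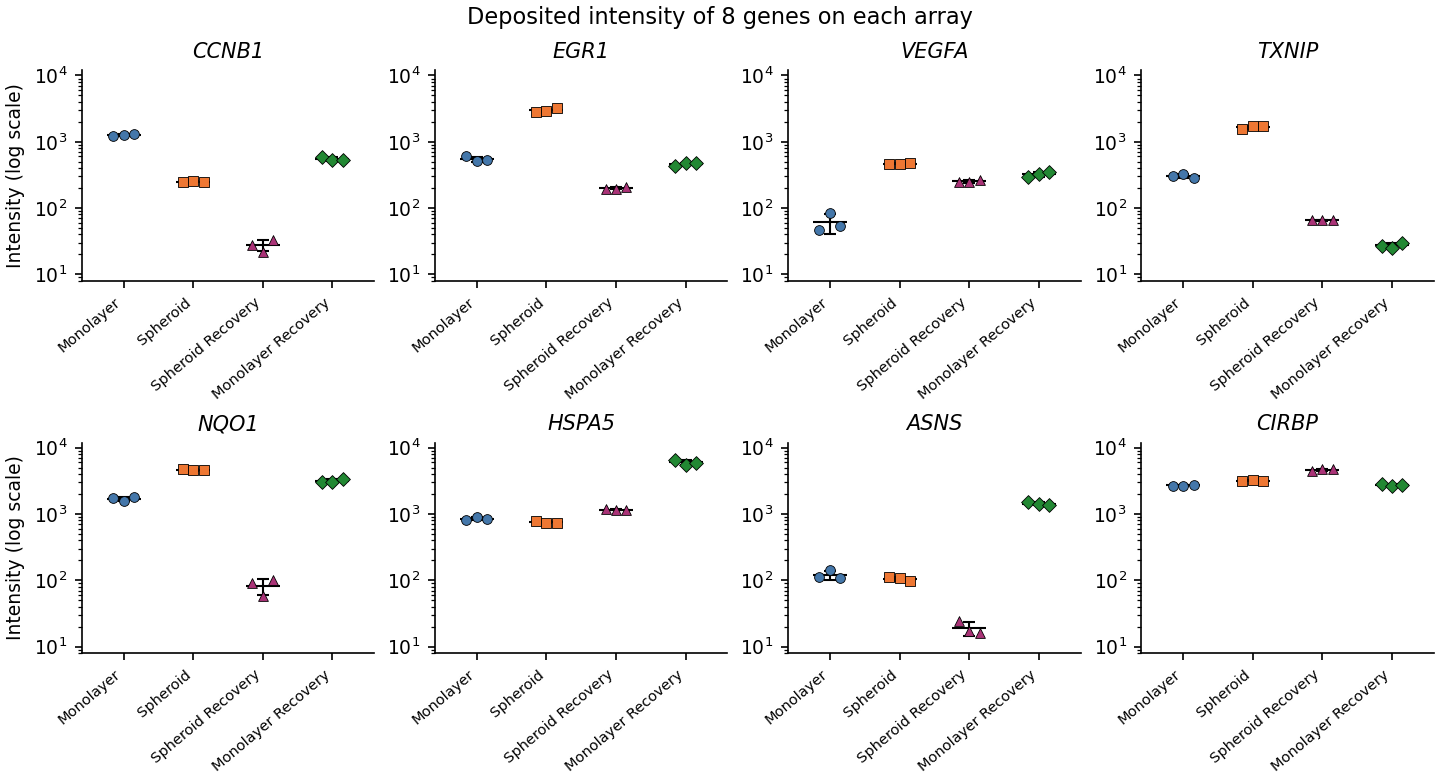
Deposited intensity (vertical, log scale) of 8 genes in the 4 groups (horizontal), with a point per array, and a bar and whiskers for the mean and SD of 3 arrays. NQO1 reads 4664 in Spheroid and 83 in Spheroid Recovery, HSPA5 reads 853 in Monolayer and 6010.0 in Monolayer Recovery, and CCNB1 reads 1264 in Monolayer and 27.7 in Spheroid Recovery.

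Spheroid Recovery was compared with Spheroid as the step that followed it in the procedure. Antioxidant, matrix and interferon-stimulated genes were lower, along with mitosis genes, but none of these calls held: adjusted p = 0.121, 0.0803, 0.309 and 0.0803 in that order with an estimated correlation. AKR1B10, an aldo-keto reductase, fell from 2220.0 to 17.7 (-6.05 ± 0.07) and the quinone reductase NQO1 from 4664 to 83 (-5.59 ± 0.11). SYNDIG1, a synapse protein, changed by -5.30 ± 0.08, TNFRSF11B by -5.25 ± 0.13 and the angiopoietin ANGPT1 by -5.22 ± 0.10, as changes on the log2 scale. The largest rises were in uridine phosphorylase UPP1 (4.34 ± 0.10), MATR3 (4.13 ± 0.09), the pseudogene DPH3P1 (3.53 ± 0.12), the syntaxin STX3 (3.43 ± 0.14) and TTC7A, a scaffold of phosphatidylinositol 4-kinase (3.06 ± 0.10).

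Of NRF2 genes, 22 of 28 tested genes fell and 3 rose (23 and 3 adjusted over the list alone). After AKR1B10 and NQO1 came AKR1C2, a related reductase (-5.08 ± 0.07, the sign was the opposite at 1 of 2 other probe sets), for which the value without probe sets ending in _x_at was 0.07 and did not pass (adjusted p = 0.17), and the other way went MAFG, a partner of NRF2 (1.37 ± 0.10). Of collagens and matrix proteins, 21 of 35 tested genes fell and 1 rose (22 and 1 adjusted over the list alone). Among them were COL8A1 at -3.99 ± 0.14 and COL3A1 at -3.54 ± 0.07, a lower bound on the size of its fall since its Spheroid Recovery level of 6.33 was within the range of unspiked controls, against THBS1 at 1.97 ± 0.17. Of matrix remodelling enzymes, 15 of 26 tested genes fell and 5 rose (18 and 6 adjusted over the list alone). Examples were the collagenases MMP1 at -3.64 ± 0.11 and MMP13 at -3.48 ± 0.11. Of mesenchymal markers, 11 of 17 tested genes fell and 1 rose (11 and 1 adjusted over the list alone). Within this list were the transcription factor SNAI2 at -2.60 ± 0.15 and the surface glycoprotein THY1 at -2.28 ± 0.11. Of NF-kB targets, 11 of 20 tested genes fell and 1 rose (11 and 1 adjusted over the list alone), led by the adhesion molecule VCAM1 (-5.17 ± 0.09). Of hypoxia genes, 18 of 33 tested genes fell and 8 rose (18 and 8 adjusted over the list alone). The list included the stress-responsive gene NDRG1 at -2.57 ± 0.06 against STC2 at 1.99 ± 0.10. Of interferon-stimulated genes, 19 of 33 tested genes fell and 4 rose (20 and 4 adjusted over the list alone). Its members included IFITM2 at -2.46 ± 0.09 against IFIT2 at 2.12 ± 0.12. EGR1 fell from 2985 to 199 (-3.80 ± 0.08).

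Of mitosis genes, 38 of 42 tested genes fell and 0 rose (38 and 0 adjusted over the list alone), led by HMMR (-3.55 ± 0.09). Of replication genes, 24 of 38 tested genes fell and 4 rose (24 and 4 adjusted over the list alone), led by RRM2 (-5.06 ± 0.08). Of glycolysis genes, 14 of 18 tested genes fell and 1 rose (14 and 1 adjusted over the list alone), led by GPI (-1.81 ± 0.12). Of oxidative phosphorylation genes, 23 of 36 tested genes fell and 6 rose (24 and 7 adjusted over the list alone), led by NDUFB8 (-2.37 ± 0.11). Of the citric acid cycle, 11 of 18 tested genes fell and 4 rose (12 and 4 adjusted over the list alone), led by SUCLA2 (-2.95 ± 0.11). Of fatty acid synthesis genes, 7 of 12 tested genes fell and 0 rose (8 and 0 adjusted over the list alone), led by ELOVL6 (-2.31 ± 0.11, the sign was the opposite at 1 of 2 other probe sets). Of metallothioneins, 6 of 7 tested genes fell and 0 rose (6 and 0 adjusted over the list alone), led by MT1X (-1.36 ± 0.09). Of heat shock proteins, 11 of 19 tested genes fell and 2 rose (11 and 3 adjusted over the list alone), led by HSPB1 (-2.35 ± 0.09). Endoplasmic reticulum chaperones were the 1 list that was higher, as 15 of 24 tested genes rose and 6 fell (15 and 6 adjusted over the list alone), led by EDEM1 (1.65 ± 0.14).

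Camera's adjusted p was 1.57e-08 for NRF2, 8.78e-06 for matrix proteins, 0.0104 for remodelling enzymes, 0.0108 for mesenchymal markers, 0.0462 for NF-kB, 0.0249 for hypoxia, 0.00156 for interferon, 6.84e-14 for mitosis and 0.00231 for replication. It was 0.000223 for glycolysis, 0.00608 for oxidative phosphorylation, 0.0457 for the citric acid cycle, 0.02 for fatty acid synthesis, 0.00231 for metallothioneins, 0.0142 for heat shock proteins and 0.02 for endoplasmic reticulum chaperones. In the same order, adjusted p = 0.121, 0.0803, 0.121, 0.25, 0.25, 0.351, 0.309, 0.0803, 0.309, 0.25, 0.536, 0.499, 0.25, 0.202, 0.309 and 0.202 with an estimated correlation. None of these 16 calls held. NF-kB targets did not pass after median centring (adjusted p = 0.0632) or without Monolayer Recovery replicate 1 (0.054), Monolayer replicate 2 (0.0522), Spheroid Recovery replicate 2 (0.0643) or Spheroid replicate 2 (0.0617). Endoplasmic reticulum chaperones did not pass after median centring (0.0632), nor the citric acid cycle without Spheroid Recovery replicate 2 (0.069) or Spheroid replicate 2 (0.0616). With only NM_ probe sets the citric acid cycle (adjusted p = 0.47), replication (0.47), endoplasmic reticulum chaperones (0.155), fatty acid synthesis (0.205), mesenchymal markers (0.926) and NF-kB targets (0.188) no longer passed.

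Genes named as changed had adjusted p of at most 2.76e-09. In all, 7369 genes passed, 3261 higher and 4108 lower. Of these 705 and 1480 changed by at least 2-fold. The arrays did not overlap for 54.4% of genes, where chance gives 10%. Higher genes made up 44.3% of those called. After median centring, which moved the median change of all genes from 0.02 to 0.19, 11445 genes passed and 71.1% of them were higher. Beside these changes, the ACTB control ratio was 4.97 in Spheroid Recovery and 4.62 in Spheroid, and the HUMISGF3A ratio 1.56 and 2.09.

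Monolayer Recovery was compared with Spheroid Recovery as the outgrowth step. Amino acid response, antioxidant, division and matrix genes were higher in the outgrown cells and lysosomal genes were lower. Of these only mitosis held with an estimated correlation (0.0284), while adjusted p = 0.101 for ATF4, 0.204 for NRF2, 0.227 for replication, 0.132 for matrix and 0.172 for lysosome with an estimated correlation. DDIT4 rose from 53 to 3455 (5.66 ± 0.08), ASNS by 5.38 ± 0.11, AKR1B10 by 5.19 ± 0.07, RRM2 by 5.09 ± 0.08 and NQO1 by 5.01 ± 0.11. The largest falls were in UPP1 (-4.29 ± 0.10), SLF2 (-4.03 ± 0.12, the sign was the opposite at 3 of 3 other probe sets), MATR3 (-3.81 ± 0.09), SNX30 (-3.77 ± 0.13) and the lectin gene CLEC2B (-3.71 ± 0.09).

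Of ATF4 genes, 24 of 28 tested genes rose and 1 fell (24 and 1 adjusted over the list alone), with PSAT1, an enzyme of serine synthesis, at 4.13 ± 0.09 after DDIT4 and ASNS. Of aminoacyl-tRNA synthetases, 15 of 17 tested genes rose and 0 fell (15 and 0 adjusted over the list alone), led by AARS1 (2.89 ± 0.11). Of endoplasmic reticulum chaperones, 19 of 24 tested genes rose and 3 fell (19 and 3 adjusted over the list alone). In this list were PDIA4 at 3.13 ± 0.07 and MANF, a secreted stress-induced factor, at 3.07 ± 0.06, and HSPA5 stood at 2.35 ± 0.06. Of mitosis genes, 40 of 42 tested genes rose and 0 fell (41 and 0 adjusted over the list alone). Members included HMMR at 4.02 ± 0.09 and the abscission protein CEP55 at 3.85 ± 0.08. Of replication genes, 24 of 38 tested genes rose and 5 fell (24 and 5 adjusted over the list alone). Of NRF2 genes, 18 of 28 tested genes rose and 5 fell (18 and 5 adjusted over the list alone), with SOD2 the other way at -1.83 ± 0.06. The adjusted p from camera was 7.95e-20 for mitosis and 4.26e-06 for endoplasmic reticulum chaperones, which both held with an estimated correlation (adjusted p = 0.0284 and 0.0284). It was 2.41e-09 for ATF4 genes, 1.08e-06 for synthetases, 0.000671 for replication and 0.000353 for NRF2 genes. In that order, adjusted p = 0.101, 0.172, 0.227 and 0.204 with an estimated correlation.

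Of collagens and matrix proteins, 18 of 35 tested genes rose and 4 fell (18 and 4 adjusted over the list alone), led by COL8A1 (3.30 ± 0.14). Of actin and SRF/YAP targets, 20 of 27 tested genes rose and 3 fell (20 and 3 adjusted over the list alone), led by MYH10 (3.04 ± 0.10). Of glycolysis genes, 13 of 18 tested genes rose and 1 fell (13 and 1 adjusted over the list alone), led by GPI (1.84 ± 0.12). Of oxidative phosphorylation genes, 20 of 36 tested genes rose and 5 fell (22 and 6 adjusted over the list alone), led by NDUFB8 (2.62 ± 0.11). Of cholesterol synthesis genes, 13 of 18 tested genes rose and 1 fell (14 and 1 adjusted over the list alone), among them the sterol carrier STARD4 (1.52 ± 0.14), a lower bound since its Spheroid Recovery level of 7.33 was within the range of unspiked controls. Of fatty acid synthesis genes, 7 of 12 tested genes rose and 1 fell (8 and 1 adjusted over the list alone), led by ELOVL6 (2.55 ± 0.11, the sign was the opposite at 1 of 2 other probe sets). Of metallothioneins, 6 of 7 tested genes rose and 0 fell (6 and 0 adjusted over the list alone), led by MT1E (1.53 ± 0.10). Of heat shock proteins, 11 of 19 tested genes rose and 2 fell (11 and 3 adjusted over the list alone), led by HSPD1 (2.46 ± 0.07, the sign was the opposite at 1 of 2 other probe sets). Of autophagy and lysosome genes, 22 of 35 tested genes fell and 5 rose (22 and 5 adjusted over the list alone), led by ASAH1 (-2.08 ± 0.12) and LAMP2 (-1.92 ± 0.09). Of cold-inducible genes, 5 of 6 tested genes fell and 1 rose (5 and 1 adjusted over the list alone), led by SRSF5 (-1.56 ± 0.12), and CIRBP stood at -0.77 ± 0.05 (the sign was the opposite at 2 of 4 other probe sets). RBM3 stood at -0.55 ± 0.06 (the sign was the opposite at 1 of 1 other probe sets), and at -0.12 with the mean of all its probe sets, which did not pass (adjusted p = 0.11).

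For these lists camera's adjusted p was 0.00257 (matrix), 9.45e-05 (actin), 0.000112 (glycolysis), 0.0282 (oxidative phosphorylation), 0.00202 (cholesterol), 0.00521 (fatty acids), 0.000918 (metallothioneins), 0.0282 (heat shock), 0.000541 (lysosome) and 0.0323 (cold-inducible). In the same order, adjusted p = 0.132, 0.132, 0.189, 0.627, 0.0754, 0.147, 0.142, 0.316, 0.172 and 0.227 with an estimated correlation. Cold-inducible genes did not pass after median centring (adjusted p = 0.0719), nor oxidative phosphorylation without Monolayer Recovery replicate 1 (0.0768). With only NM_ probe sets lysosome (adjusted p = 0.0527), cholesterol (0.0588), replication (0.104), fatty acids (0.17) and oxidative phosphorylation (0.186) no longer passed. No gene named as changed had an adjusted p above 4.37e-08. In all, 7447 genes passed, 3904 higher and 3543 lower. Of these 1179 and 1112 changed by at least 2-fold. The arrays did not overlap for 51.6% of genes, where chance gives 10%. Higher genes made up 52.4% of those called, and 39.5% after median centring. The ACTB control ratio was 3.85 in Monolayer Recovery and 4.97 in Spheroid Recovery, and the HUMISGF3A ratio 2.31 and 1.56, beside all of these lists.

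Monolayer Recovery was compared with Spheroid to ask how far the regrown cells had moved from the spheroid state. STC2 rose from 91.7 to 2123 (4.31 ± 0.10), ASNS by 3.58 ± 0.11, the pentraxin PTX3 by 3.56 ± 0.11, CCN1 by 3.56 ± 0.10 and PCLO, which encodes piccolo, by 3.40 ± 0.10. The largest falls were in TXNIP (-5.27 ± 0.09), PI15 (-4.33 ± 0.14), CCL8 (-3.72 ± 0.09), the copper-binding ceruloplasmin gene CP (-3.67 ± 0.12) and COL3A1 (-3.54 ± 0.07). For COL3A1 the size of the fall is a lower bound, since its Monolayer Recovery level of 6.33 was within the range of unspiked controls.

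Of endoplasmic reticulum chaperones, 24 of 24 tested genes rose and 0 fell (24 and 0 adjusted over the list alone). Among them were HSPA5 at 2.96 ± 0.06 and the large chaperone HYOU1 at 2.75 ± 0.10. Of ATF4 genes, 23 of 28 tested genes rose and 2 fell (24 and 2 adjusted over the list alone), led by STC2 and ASNS. Of mitosis genes, 36 of 42 tested genes rose and 0 fell (36 and 0 adjusted over the list alone), led by CDC20 (1.23 ± 0.11). Of cholesterol synthesis genes, 15 of 18 tested genes rose and 0 fell (15 and 0 adjusted over the list alone). Examples were STARD4 at 1.504 ± 0.14, a lower bound since its Spheroid level of 7.67 was within the range of unspiked controls, and the sterol oxidase MSMO1 at 1.30 ± 0.08. These 4 lists passed at 4.09e-22, 1.13e-16, 3.18e-16 and 5.77e-10 (camera's adjusted p, in that order) and held with an estimated correlation (adjusted p = 0.000423, 0.027, 0.0282 and 0.00209).

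Of aminoacyl-tRNA synthetases, 13 of 17 tested genes rose and 0 fell (13 and 0 adjusted over the list alone), led by GARS1 (2.32 ± 0.08). Of actin and SRF/YAP targets, 13 of 27 tested genes rose and 4 fell (13 and 4 adjusted over the list alone), led by CCN1. Of ribosome biogenesis genes, 12 of 27 tested genes rose and 1 fell (12 and 1 adjusted over the list alone), led by NCL (0.60 ± 0.08). Of proteasome genes, 12 of 26 tested genes rose and 2 fell (13 and 2 adjusted over the list alone), led by PSMD14 (0.56 ± 0.06). Of neuronal markers, 6 of 16 tested genes rose and 1 fell (6 and 1 adjusted over the list alone). Within this list were the microtubule genes MAP2 at 1.75 ± 0.11 and TUBB3 at 0.95 ± 0.08. Lower were NRF2 genes, of which 18 of 28 tested genes fell and 1 rose (20 and 2 adjusted over the list alone), led by SOD2 (-2.37 ± 0.06), and interferon-stimulated genes, of which 19 of 33 tested genes fell and 1 rose (19 and 1 adjusted over the list alone), led by IFITM1 (-2.04 ± 0.07). Of hypoxia genes, 20 of 33 tested genes fell and 4 rose (21 and 4 adjusted over the list alone). The list included SLC2A3 at -2.05 ± 0.09 and the hormone gene STC1 at -2.04 ± 0.08 against STC2. Of TGF-beta targets, 12 of 20 tested genes fell and 2 rose (13 and 2 adjusted over the list alone), led by the pseudoreceptor BAMBI (-2.46 ± 0.09). Of matrix remodelling enzymes, 13 of 26 tested genes fell and 4 rose (14 and 4 adjusted over the list alone). Its members included MMP1 at -2.86 ± 0.11 and MMP13 at -2.39 ± 0.11. Of collagens and matrix proteins, 17 of 35 tested genes fell and 5 rose (19 and 5 adjusted over the list alone), with FN1 at -2.16 ± 0.08 (the sign was the opposite at 1 of 4 other probe sets) after COL3A1. Of autophagy and lysosome genes, 17 of 35 tested genes fell and 4 rose (19 and 4 adjusted over the list alone), led by TPP1, a lysosomal peptidase (-1.20 ± 0.11). EGR1 stood at -2.65 ± 0.08.

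For these lists camera's adjusted p was 1.79e-10 (synthetases), 0.000108 (actin), 0.000592 (ribosome biogenesis), 0.00427 (proteasome), 0.0238 (neuronal), 6.53e-06 (NRF2), 5.3e-05 (interferon), 0.00034 (hypoxia), 0.00323 (TGF-beta), 0.00723 (remodelling), 0.0209 (matrix) and 0.00723 (lysosome). In the same order, adjusted p = 0.0933, 0.0975, 0.225, 0.262, 0.105, 0.115, 0.21, 0.169, 0.0675, 0.0822, 0.169 and 0.26 with an estimated correlation. After quantile normalization lysosome (adjusted p = 0.0606) and neuronal markers (0.0694) did not pass, nor did neuronal markers without Monolayer Recovery replicate 2 (0.0524), and with only NM_ probe sets matrix proteins (0.31), neuronal markers (0.0914) and TGF-beta targets (0.0502) did not. The genes named as changed had adjusted p up to 3.13e-06. In all, 5947 genes passed, 2282 higher and 3665 lower. Of these 196 and 499 changed by at least 2-fold. The arrays did not overlap for 47.2% of genes, where chance gives 10%. Higher genes made up 38.4% of those called, 49.4% after quantile normalization and 56.5% after median centring. Beside these changes, the ACTB control ratio was 3.85 in Monolayer Recovery and 4.62 in Spheroid, and the HUMISGF3A ratio 2.31 and 2.09.

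The comparisons were then set side by side, since the series title names recovery. Of the 3566 genes higher in Spheroid than in Monolayer, 2727 (76.5%) were called lower in Monolayer Recovery than in Spheroid, and 1633 (45.8%) were still called higher in Monolayer Recovery than in Monolayer. Of the 4176 lower genes, 1329 (31.8%) were called higher in Monolayer Recovery than in Spheroid and 2692 (64.5%) were still called lower than in Monolayer. The gap between higher and lower genes narrowed with other scaling: 67.2% and 44.8% were called back after quantile normalization, and 69.1% and 47.1% after median centring. After median centring 59.2% of higher and 60.3% of lower genes were still called in the same direction against Monolayer. These comparisons share the Spheroid arrays, which favours opposite calls. Independent lists would give 881.2 and 642.5 opposite calls. The log2 changes correlated at -0.75 with a covariance of -0.22, against -0.50 and -0.0046 for unchanged groups simulated with the same sharing. TXNIP, STC2 and GARS1 had moved back past the Monolayer level, as had 202 higher and 144 lower genes in all. PI15 and CCL8 were also called in the opposite direction in Monolayer Recovery against Spheroid. Lists shared by the 3 comparisons with Monolayer, all lower, included mitosis, replication, heat shock proteins, proteasome and metallothioneins. With an estimated correlation mitosis held in all 3, replication and heat shock proteins only in Monolayer Recovery, and proteasome and metallothioneins in 0.

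Spheroid and Spheroid Recovery, each against Monolayer, shared 2044 higher and 2813 lower genes, where lists independent of each other would share 850.1 and 1370.0, and 1105 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated at 0.54 with a covariance of 0.30. Unchanged groups simulated against the same Monolayer arrays gave a correlation of 0.50 and a covariance of 0.0046. For Spheroid and Monolayer Recovery against Monolayer the correlation was 0.68 and the covariance 0.18, with 1633 genes higher and 2692 lower in both (564 and 1049 for independent lists). The 3 shared arrays were not split between the comparisons, so part of the excess may come from them.

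Of the 39 lists, 9 passed camera in 0 of the 6 comparisons. The closest were immediate early genes in Spheroid against Monolayer, where 17 of 35 tested genes rose and 7 fell (17 and 7 adjusted over the list alone, adjusted p = 0.0611), and replication-dependent histones in Monolayer Recovery against Spheroid Recovery, where 1 of 10 rose and 6 fell (2 and 6 adjusted over the list alone, adjusted p = 0.0855). The lowest adjusted p was 0.116 for oligodendrocyte markers, 0.117 for astrocyte markers, 0.245 for epithelial markers, 0.248 for neural and glioma stem cell markers, 0.419 for endothelial and pericyte markers, 0.492 for leukocyte markers and 0.714 for apoptosis regulators. Among panel genes, the transcription factor MYC read 21.7 in Monolayer, 22.3 in Spheroid and 23 in both recovery groups.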

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

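The tests of the ACTB ratio, of compression among probe sets with opposite changes, of array scaling, of carry-over and of the EST share in Spheroid and Monolayer Recovery were chosen after the results were seen. Those of EST probe sets in Spheroid Recovery, of long non-coding genes and of ARRDC4 were added for patterns seen in the results. Only their predictions were written before those tests were run. The control probe set AFFX-M27830_5_at, outside the comparisons of genes, read 63.3 in Spheroid Recovery against 8.33 in Monolayer, a signal in data the report does not use. It was the 1 of 34 control probe sets looked at that lay at least 2-fold above Monolayer. Of the 7001 probe sets without a single gene name that passed the same limit on mean intensity as the genes, 1535 were called higher and 1164 lower in Spheroid Recovery than in Monolayer, a further signal outside the genes compared. Groups of 3 arrays were not tested for outlying samples.

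The wider ACTB ratio was set against a general loss of 5' ends, which would widen the HUMISGF3A ratio too. In Spheroid Recovery that ratio widened by 0.0129 ± 0.158 and the GAPDH ratio by 0.031 ± 0.042 (SE). Both lay below 25% of the ACTB widening, a limit chosen after the results were seen. These values argue against a general loss there, but they rest on 2 control transcripts. The 3' intensity of HUMISGF3A itself fell from 443 in Monolayer to 145 in Spheroid Recovery, so a general loss was not excluded. In Spheroid it widened by 0.54 while GAPDH did not widen (-0.06), and in Monolayer Recovery by 0.76, so that a general loss and a change of ACTB itself cannot be told apart in these 2 groups. No biological explanation was tested.

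In Spheroid Recovery against Monolayer, 95 of 6992 genes had probe sets that moved in opposite directions by at least 1 (log2 scale). There were 8 such genes in Spheroid and 0 in Monolayer Recovery. These were 3.87%, 0.58% and 0% of the 2457, 1379 and 446 genes with a probe set that moved by at least 1. Compression of dim probe sets keeps the sign of a change by definition, so a count of opposite changes cannot test it. The count is also silent on most of the 622 genes whose probe sets spread by at least 2 in Spheroid Recovery. Probe sets designed on EST sequences stood above those on NM_ transcripts by a median of 0.0891, and by 0.0618 where they were as bright. In Spheroid these medians were 0.118 and 0.211 and in Monolayer Recovery 0.0498 and 0.0654, so the excess was not particular to Spheroid Recovery. Retained unspliced or extended RNA predicted a median above those of both other groups, which was not met. That cause was left open by a condition outside the prediction. The Spheroid Recovery median minus that of Spheroid was -0.0293 (bootstrap over genes, 95% interval -0.0573 to 0.0015). Retained RNA and compression thus cannot be told apart over all genes. Among 262 genes whose probe sets spread by at least 2, the EST ones were higher in 64.9% (exact p = 1.66e-06 against an equal share). This is the direction that retained RNA predicts, but over all 1792 genes with both kinds the share was already 57.2%. Among genes with such a spread, it was 60.7% of 61 in Spheroid (exact p = 0.124) and 3 of 5 in Monolayer Recovery. The excess was therefore not shown to be particular to Spheroid Recovery. Long non-coding genes were 6.36% of higher and 3% of lower genes (odds ratio 2.20), against 6.35% and 1.48% in Monolayer Recovery (4.53) and 4.32% and 3.64% in Spheroid (1.20, Fisher's exact p = 0.129). They were 1292 of the 14811 tested genes with an annotated type, a larger share than among called genes of either direction. The odds ratio thus compares higher with lower genes only. It was not highest in Spheroid Recovery, so the prediction for that group was not met, but no cause acting there was excluded.

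Higher endoplasmic reticulum and ATF4 genes in Monolayer Recovery were still seen after renormalization, with 0.97 as the lower of the list medians. Array medians of the tested genes were 5.81 to 5.86 in Monolayer and 5.70 to 5.75 in Monolayer Recovery. Median centring could thus move the lists only a little, and its outcome was largely fixed in advance. A shift of whole arrays of that size is too small to give the rise, but other effects of the unstated normalization were not tested. Both lists were higher in Monolayer Recovery than in Spheroid Recovery, with a lower median of 0.84. By these medians, carry-over at the Spheroid Recovery level was not enough for the whole rise. For ATF4 genes this call was lost with an estimated correlation (camera's adjusted p = 0.101). Carry-over of part of the rise was not excluded, since endoplasmic reticulum chaperones already had a median of 0.36 in Spheroid Recovery against Monolayer. Low glucose at harvest could lower both TXNIP, which changed by -2.89, and ARRDC4, which changed by -0.34 ± 0.13 (SE, adjusted p = 0.0477). The ARRDC4 change was less than the fall of 1 that was required. It was also small enough to meet the prediction written beforehand for the absence of low glucose. Allowing for its error, however, the change reached down to -0.598, which did not meet that prediction. That allowance was not part of the prediction. TXNIP fell strongly, so the glucose explanation and others cannot be told apart.

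Whether chance could give the counts was tested by splitting the arrays in other ways. By the F test, 10385 genes were called in the real grouping and at most 4067 in 99 drawn ones. Only 1 of 100 splits thus reached the real count, which argues against random labelling of these arrays alone. Arrays of a group may be technical repeats, so shuffling them cannot test chance differences between cultures, and those were not excluded. For each pair of groups 1 of 10 splits reached the real count and the highest other count was 0, and with 10 splits no smaller share was possible, so chance and a group difference cannot be told apart by this test.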

How the results depend on the processing

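The fit without the Spheroid Recovery arrays and the choice of NM_ probe sets were added after the data were seen. Of 99 list calls, 14 held with an estimated correlation, 95 after quantile normalization, 92 after median centring and 78 with NM_ probe sets, and all 99 held with fry, without a filter and with the replicate block; fry called 202 lists in all. Of 231 named gene values, 231 were the same under both offsets, quantile normalization, array weights, the replicate block and the plain fit. With the mean of all probe sets RBM3 in Spheroid against Monolayer was -0.00061 and for CIRBP, Monolayer Recovery against Monolayer, it was -0.11; the latter was -0.0094 without Monolayer Recovery replicate 1 and 0.0456 without Monolayer Recovery replicate 2, the lowest and highest with an array left out, and AKR1C2 in Spheroid Recovery against Spheroid was 0.0740 without _x_at probe sets; the cause was not tested. Spheroid Recovery against Spheroid had 11445 genes after median centring. Before centring, array medians of the tested genes were 5.61 to 5.64 in Spheroid Recovery and 5.78 to 5.83 in Spheroid. Centring therefore raised the change of every gene alike, moved the median change from 0.02 to 0.19, and the share of higher genes from 44.3% to 71.1%. In the order of the report, a 2-fold minimum left 1574, 2887, 540, 2185, 2291 and 695 genes, and treat against 1.5-fold 2114, 3578, 701, 2757, 2873 and 863, both stricter by construction. With NM_ probe sets, where fewer genes were tested, 3704, 3976, 2942, 3404, 3378 and 2443 were called, and 4837 by the F test. Leaving out each array in turn gave 6815 to 7862, 7808 to 8492, 5153 to 6191, 6740 to 7480, 6944 to 7455 and 4863 to 6074 genes, 9871 to 10432 by the F test and 97 to 101 lists. The replicate block gave 7616, 8322, 6024, 7303, 7375 and 5831 genes. Deviations of same-numbered arrays from their group means correlated at -0.289 to 0.376. In Monolayer Recovery against Spheroid Recovery 2 of 3 arrays correlated best with their own number, and 0 or 1 did in the other comparisons. With 3 arrays a group, whether the numbers pair samples cannot be settled. Between 62.0% and 77.1% of probe sets lay above the unspiked controls, which limits what dim genes can show.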

Other observations

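The tests of the ACTB ratio described above were chosen after the result was seen, and no further test was made for this part. Of the 7742 genes called in Spheroid against Monolayer, 2091 were called back in Monolayer Recovery without a call against Monolayer, and 1619 were called back but still differed from Monolayer, counts that the shared Spheroid arrays favour. Median changes against Monolayer of the genes higher in Spheroid were 0.69 in Spheroid and 0.21 in Monolayer Recovery, and of the lower genes -0.43 and -0.34.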
